A study of Mus musculus with 12 samples.

How the data were processed

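Whole-genome bisulfite libraries of mouse genomic DNA were compared: sperm, fetus, placenta, male PGCs and female PGCs, each WT and Aid-deficient, and ES cells, WT and Np95-deficient, 12 libraries in all with 1 per group. Per the labels' protocols, libraries were amplified by 15 PCR cycles, and input for PGC libraries went down to 150 ng, with scaled-down reactions and more parallel PCRs. The deposited files hold other data than counts or levels: per the labels, each line is the observation of 1 cytosine in 1 read, with chromosome, strand, coordinate and a letter for methylated or unmethylated. The authors aligned to mm9, per the submitters' processing notes. The aligner, its filters and any removal of duplicate reads are not given in the sources used here. Nothing was normalized, so the call counts are the depth. Each PGC library came as 2 runs, which were summed and counted as 1 sample. The PGC files list between 4036 and 5324 calls on the mitochondrial chromosome and the other files none, so reads of the PGC libraries may not have been aligned or filtered in the same way as the others. Mitochondrial calls were left out of every level.

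The files give no sequence context and no mm9 sequence was used here, so context was inferred from the called positions of all libraries together. A cytosine on the plus strand followed by one on the minus strand at the next base is a CpG. Adjacent cytosines of 1 strand give CC, and a plus strand cytosine with a minus strand cytosine 2 bases on and none called between gives CWG (W is A or T). Here W was inferred from the absence of a call. CGG or CCG sites whose middle base was not called can therefore enter CWG. This identified 271410 CpG sites, without any position called as cytosine on both strands or as both CpG and CC. A site is identified only if both of its strands were called in some library, so CpG sites with more calls are more often among those used, and a site called isolated below is isolated among identified sites. In simulated data with a known genome, none of 330 identified sites was wrong and the level came out at 22.1% for a true 23%. The simulated calls lay only at true cytosines, so wrong sites could not arise. All simulated CpG sites shared 1 level, so a bias from uneven coverage was not tested, nor was the CWG class.

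The level of a library is the share of methylated calls among its CpG calls on the nuclear chromosomes. Counting error is the 95% Wilson interval, at most 0.190 points either way in the PGC libraries and 0.688 points in the others. It treats calls as independent, which PCR copies and calls of 1 read are not, so the text gives the delete-one jackknife SE over blocks of 1 Mb. Upper limits for a count of 0 are 3 calls of the total and cover counting error only. Differences are in percentage points with the block jackknife over both libraries together. The runs of a PGC library were compared with each other to give the technical error of sequencing. Windows of 100 kb with at least 50 calls in both libraries were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the windows of a pair and a threshold of 0.05. CpG calls were too few for this test, so it used the calls at all cytosines. A window share is thus far below the CpG level, falls where fewer of the calls are at CpG, and the count of windows depends on depth. In simulated libraries with 200 changed windows, a 3-fold change was recovered in 42% of them at the depth of male PGCs and in 8% at that of fetus, a 2-fold change in 6% and 0%, and a 1.5-fold change in 0% of them in both, with 4 false calls in 1 of the 6 simulations and 0 in the others. The mean of the 5 Aid minus WT differences was tested with exact sign flips, and the PGC pairs against the others with exact permutation of the pair labels.

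The windows named in the text follow a rule fixed before the data were examined: of each genotype pair, the 5 windows past the threshold with the largest difference in each direction. The text gives those that carry the comparison. Windows of the ribosomal RNA gene copy, the X end and the satellite regions are described further after their values were seen. That these are ribosomal and satellite copies is background knowledge of the mm9 assembly and not taken from an annotation. Tests of promoters, of 11 gene lists and of the deleted genes were planned. They were not run, because the gene table used here is of another build (GRCm38.p6), so its coordinates do not apply. Coordinates are mm9, counted from 1. CpG density is the number of other identified CpG sites within 100 bp. For pairs of calls of 1 molecule, calls of the same run on 1 strand at most 15 bp apart were used, at positions called once and sites with at most 30 calls. No read name was used to tie them, so some pairs can come from different reads.

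Alternatives fixed before the data were examined were 1 call per position and strand, leaving out positions with over 10 calls, equal weight of windows, positions called in both libraries, autosomes only, each strand, each run, leaving out each tissue pair, and other minimum calls, window sizes, depth and centring for the window counts. Added after seeing the data were leaving out sites with over 30 calls, isolated sites, subtracting the CC background, requiring the opposite strand from a library outside the pair, a mean over windows of 10 Mb, and window counts without heavily called positions or without CC calls. Flow cells were read from run identifiers: the 4 PGC libraries shared 2 flow cells, WT fetus and WT placenta shared another, and each remaining library had its own. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and numba 0.67.0, with figures in matplotlib 3.10.9.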

Results

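DNA methylation was measured by bisulfite sequencing in mouse primordial germ cells (PGCs, the embryonic precursors of sperm and eggs) and in other tissues of wild-type (WT) animals and of animals lacking Aid, the activation-induced cytidine deaminase. Bisulfite converts unmethylated cytosine and leaves methylated cytosine unchanged, so each read calls the cytosines it covers as methylated or unmethylated. WT and Aid-deficient libraries were made from male PGCs, female PGCs, whole fetus, placenta and sperm. Embryonic stem (ES) cells were sequenced with and without Np95 (Uhrf1), a protein needed to copy CpG methylation at replication. Each of these 12 groups had 1 library, so no difference below has a replicate check, and each test on calls compares 2 libraries and not the conditions.

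The PGC libraries held between 24563146 and 25692124 cytosine calls each, from 2 sequencing runs, and the other libraries between 2032660 and 5983361. Calls at identified CpG sites numbered 206228 to 266924 in the PGC libraries and 12790 to 35672 in the others. Calls were concentrated: the 50 regions of 10 kb with the most calls held 45.1% of all CpG calls, and in single libraries the leading 50 held from 11.02% in Aid fetus to 53.6% in Aid female PGCs. Levels are therefore given over all CpG calls with the block jackknife standard error (SE), and beside them with 1 call per position and strand. At CC positions, which carry almost no methylation in mammals, the methylated share was 0.0973% to 0.145% in the PGC libraries, 0.0796% to 0.310% in fetus and placenta, 0.139% and 0.510% in sperm, and 0.659% and 1.12% in the ES cells. The Y chromosome took 0.112% and 0.0901% of the calls of WT and Aid male PGCs but 0.00171% and 0.00149% of those of the female PGCs, in keeping with the sexes given by the labels.

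WT germ cells were compared with WT fetus as a somatic reference. In WT male PGCs 26.4% of CpG calls were methylated (SE 4.20), and in WT female PGCs 21.4% (SE 3.48), against 73.3% (SE 2.66) in WT fetus. With 1 call per position and strand the levels were 17.2% (SE 0.444), 9.45% (SE 0.538) and 76.7% (SE 0.518). The PGC levels thus lay 46.9 (SE 4.55) and 51.9 (SE 4.17) percentage points below fetus over all calls. WT placenta stood between them at 43.7% (SE 0.935), and WT sperm at 80.4% (SE 4.47), or 86.5% (SE 0.523) with 1 call per position. WT ES cells had 82.0% (SE 1.73). The PGC libraries came from other flow cells than WT fetus, and only their files held mitochondrial calls. A part of the difference between PGCs and fetus due to batch or alignment was therefore not told apart.

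**Figure D1:**
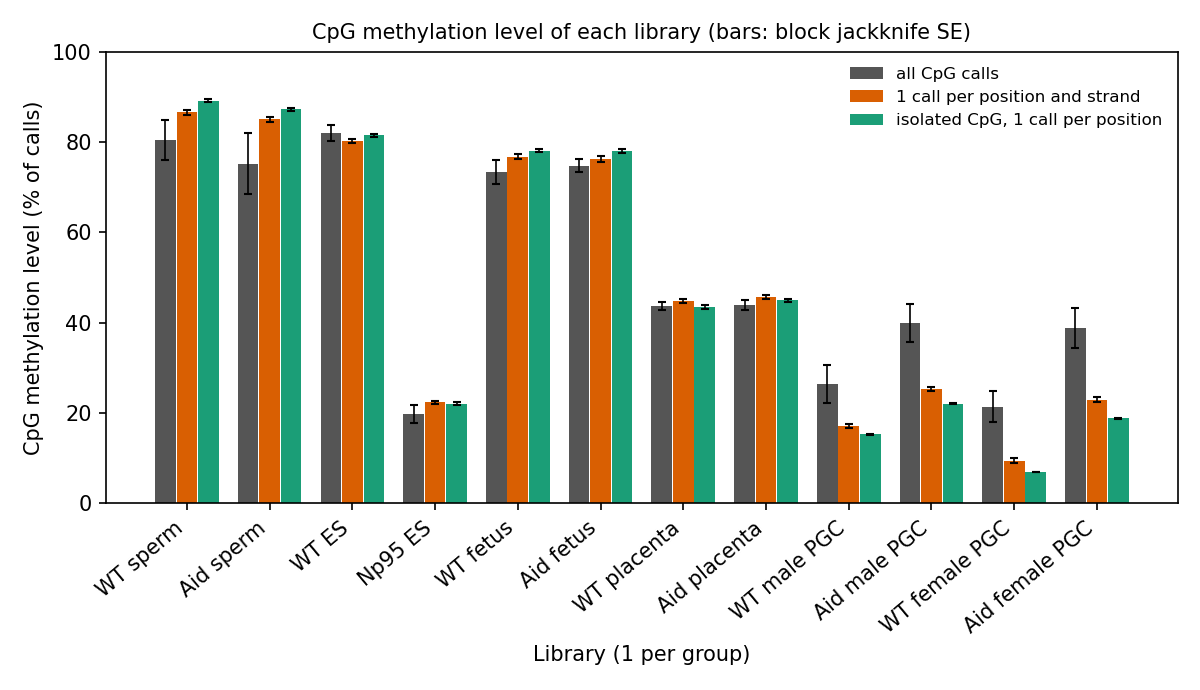
CpG methylation level (percent of calls) of the 12 libraries over all CpG calls, with 1 call per position and strand, and at isolated CpG sites with at most 30 calls over all libraries, 1 call per position. Error bars are block jackknife SEs. WT female PGCs are the lowest library with 1 call per position, at 9.45%, and the Aid PGC libraries reach 25.3% in males and 22.9% in females.

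The lower level of WT PGCs than of WT fetus was spread over the genome. Among windows of 100 kb, tested on calls at all cytosines, 14784 of 24785 differed between WT male PGCs and WT fetus (Fisher's exact test per window, Benjamini-Hochberg adjusted p under 0.05), 14771 of them lower in PGCs and 13 higher. For WT female PGCs 18688 of 24774 differed, 18669 lower and 19 higher. Tested against the genome-wide difference of the pair, 67 windows differed for males, 35 higher and 32 lower, and 221 for females, 131 higher and 90 lower. With both libraries thinned to the depth of the shallowest, 4 and 8 windows differed, so the counts are set by depth as well as by size. The share of all cytosine calls also depends on how many of them are at CpG, so a window can differ without a difference in CpG level.

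Some repeated regions were highly methylated in WT PGCs. At the copy of the ribosomal RNA gene on chromosome 17 (39970001 to 39990000, mm9), 64.1% of 6326 CpG calls were methylated in males and 65.9% of 9616 in females, against 59.9% of 706 in WT fetus. Near the end of the X chromosome (166400001 to 166450000) the values were 87.3% of 1886 calls, 87.7% of 3145 and 93.3% of 149. At 4 satellite regions, on chromosomes 2, 9 and 12, the levels were 33.5% of 77055 calls and 25.0% of 87513, against 82.2% of 2070 in fetus. These regions were chosen after their values were seen, and their repeated copies cannot be separated in these files.

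Female PGCs were less methylated than male PGCs in WT. The difference was -4.99 points (SE 1.80) over all calls and -7.72 points (SE 0.196) with 1 call per position. Windows that differed numbered 1696 of 25335, 1592 of them lower in females and 104 higher. Tested against the genome-wide difference, 386 windows differed, 227 higher and 159 lower. Between the Aid libraries the sexes were closer, at -1.06 points (SE 1.17) over all calls and -2.40 points (SE 0.222) with 1 call per position. Of 25340 windows 1516 differed there, 932 higher and 584 lower in females, but with 1 call per position the count was 43, 25 higher and 18 lower.

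The PGC pairs addressed whether Aid deficiency affects erasure. Both Aid PGC libraries were more methylated than their WT counterparts. Male PGCs had 39.9% (SE 4.28) in Aid and 26.4% in WT, a difference of 13.5 points (SE 4.96), and female PGCs 38.9% (SE 4.45) and 21.4%, a difference of 17.5 points (SE 3.85). With 1 call per position and strand the levels were 25.3% and 17.2% in males, a difference of 8.17 points (SE 0.211), and 22.9% and 9.45% in females, a difference of 13.5 points (SE 0.195). At CpG sites with no other identified CpG within 100 bp and at most 30 calls over all libraries, with 1 call per position, a choice made after seeing the data, the differences were 6.79 points (SE 0.185) and 11.9 points (SE 0.168). The 2 runs of a PGC library differed by at most 1.66 points over all calls and 0.263 points with 1 call per position.

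The higher level of the Aid PGCs was spread over the genome. With 1 call per position it was found on 19 of 19 autosomes in both sexes, from 5.81 points (SE 0.835) on chromosome 18 to 9.71 (SE 0.871) on chromosome 7 in males, and from 11.8 (SE 0.887) on chromosome 19 to 15.2 (SE 1.05) on chromosome 10 in females. Among sites with at most 30 calls over all libraries, with 1 call per position, isolated CpG went from 15.3% in WT to 22.1% in Aid male PGCs, and from 6.94% to 18.8% in female PGCs. All 10 class differences of the 2 PGC pairs were above 0, over all calls and with 1 call per position, against 5 and 3 of the 15 in fetus, placenta and sperm. Sites with over 5 other CpG within 100 bp went from 53.2% to 69.3% (difference 16.2, SE 5.22) and from 54.2% to 70.8% (difference 16.6, SE 3.29) under the same limit of 30 calls, which was chosen after seeing the data. Without that limit, and with 1 call per position, they went from 70.7% to 77.8% (difference 7.04, SE 3.01) and from 70.8% to 78.3% (difference 7.51, SE 2.11). On the X chromosome, also with 1 call per position and without that limit, the levels were 31.3% and 39.8% in WT and Aid males, and 23.2% and 38.6% in females, against 9.07% and 22.5% on the autosomes of WT and Aid females. With the limit of 30 calls the X levels were 21.6% and 30.7% in males and 16.6% and 32.9% in females, against 8.24% and 21.7% on the autosomes of females. Over all calls, the level at the satellite regions was 33.5% and 38.1% in WT and Aid males and 25.0% and 35.1% in females. At the ribosomal RNA gene copy it was 64.1% and 73.5% in males but 65.9% and 66.9% in females, and at the X end 87.3% and 89.5% in males and 87.7% and 88.9% in females.

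**Figure D2:**
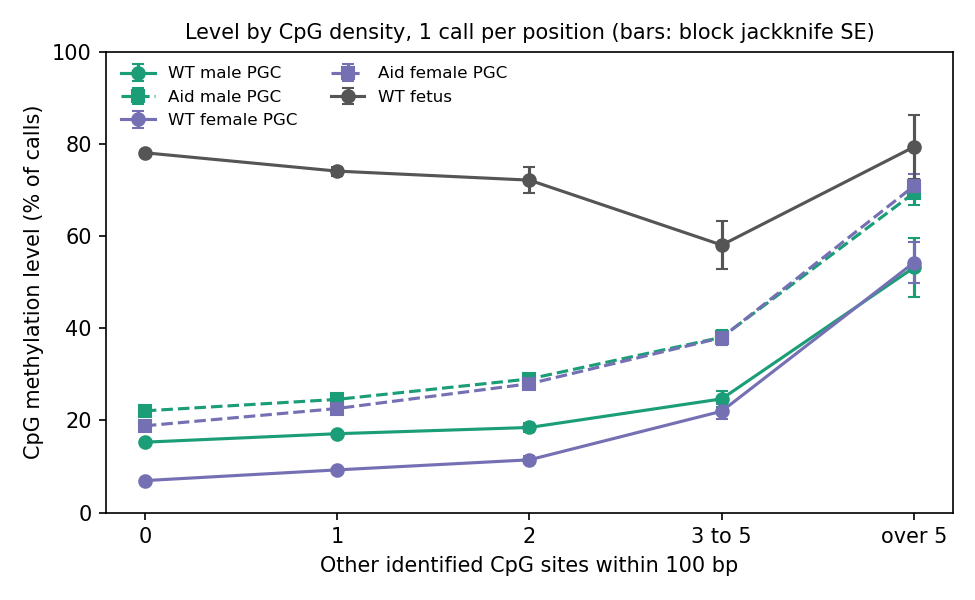
CpG methylation level (percent of calls, 1 call per position, sites with at most 30 calls over all libraries) against the number of other identified CpG sites within 100 bp, for the 4 PGC libraries and WT fetus. Points are levels and bars block jackknife SEs. Each Aid PGC library lies above the WT library of its sex in every class, from 22.1% against 15.3% at isolated CpG of males to 70.8% against 54.2% in the densest class of females.

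By window, 3196 of 25350 differed between Aid and WT male PGCs, 3152 higher in Aid and 44 lower. In female PGCs 9363 of 25352 differed, 9326 higher and 37 lower. The same test between the 2 runs of 1 library gave 24 and 169 windows in WT and Aid males and 40 and 283 in WT and Aid females, but a run holds fewer calls than a library, from 12015850 to 13264819, and these counts show sequencing noise only. Against the genome-wide difference the counts were 679 windows in males, 358 higher and 321 lower, and 1150 in females, 615 higher and 535 lower. Counting each position once, 1027 and 6671 windows differed, and thinned to the shallowest library 5 and 5, since a thinned window holds few methylated calls.

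Among the named windows, the largest rise in male PGCs was on chromosome 17 from 6400001 to 6500000, where 49 of 182 calls were methylated in Aid (26.9%) and 16 of 315 in WT (5.08%), with an adjusted p of 2.20e-09 in Fisher's exact test. Of these calls, 75 in Aid and 56 in WT lay in the same 1 kb, where 50.7% and 26.8% were methylated. The window on the X chromosome from 57700001 to 57800000 had 110 of 581 calls methylated (18.9%) against 9 of 391 (2.30%), where 143 of the Aid calls lay at 26 positions of 1 kb and were 68.5% methylated. On chromosome 16 from 57300001 to 57400000 the shares were 29.96% of 4036 calls and 11.02% of 1796, but 2783 of the Aid calls lay in 1 kb, and without positions called over 10 times the difference was -3.38 points. Falls were smaller: on chromosome 13 from 27400001 to 27500000 8 of 790 calls (1.01%) were methylated in Aid against 57 of 821 (6.94%) in WT, with 74 of the WT calls in 1 kb at 73.0% methylation, and on the X chromosome from 76200001 to 76300000 2 of 348 (0.575%) against 17 of 355 (4.79%). Of the 10 named male windows, 2 kept their call with 1 call per position, those on chromosome 17 from 6400001 and on the X chromosome from 76200001.

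In female PGCs the window on chromosome 6 from 47600001 to 47700000 had 19 of 64 calls methylated in Aid (29.7%) and 0 of 69 in WT, which allows a share of up to 4.35%. Of these Aid calls 48 lay at 5 positions of 1 kb and were 37.5% methylated. The window on chromosome 13 from 66000001 to 66100000 had 68 of 241 calls (28.2%) against 7 of 186 (3.76%), and that on chromosome 4 from 145400001 to 145500000 had 110 of 402 (27.4%) against 10 of 181 (5.52%), with 267 of the Aid calls in 1 kb. The largest fall was on chromosome 6 from 123300001 to 123400000, with 0 of 187 calls in Aid, which allows up to 1.60%, against 13 of 210 in WT (6.19%). Of the 9 named female windows with enough calls, 5 kept their call with 1 call per position, among them those on chromosome 13 from 66000001 and on chromosome 6 from 123300001. The window on chromosome 6 from 47600001 had too few calls for that test.

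The fetus, placenta and sperm pairs addressed whether Aid deficiency changes methylation outside PGCs. Over all CpG sites together, fetus and placenta differed little between genotypes. Aid fetus had 74.7% (SE 1.41) and WT fetus 73.3%, a difference of 1.40 points (SE 1.35) over all calls, -0.526 points (SE 0.458) with 1 call per position. Aid placenta had 43.9% (SE 1.11) and WT placenta 43.7%, a difference of 0.263 points (SE 0.584) over all calls, 0.876 points (SE 0.586) with 1 call per position and 1.54 points (SE 0.520) at isolated CpG with at most 30 calls. At CpG-dense sites with 1 call per position Aid fetus was lower: 46.4% of 112 calls against 77.5% of 699 with over 5 other CpG within 100 bp (difference -31.1, SE 4.08), and -16.2 points (SE 5.68) with 3 to 5 others. Over all calls these differences were -7.08 (SE 25.6) and 3.81 (SE 6.55), and for sites with at most 30 calls and 1 call per position -28.1 (SE 13.8) and -16.4 (SE 7.60). With 1 call per position, Aid and WT fetus had 15564 and 22587 CpG calls in all, a smaller gap than 112 and 699. The dense sites covered may thus differ, and a lower level was not told apart from uneven recovery. Aid sperm had 75.2% (SE 6.69) and WT sperm 80.4%, a difference of -5.15 points (SE 2.28) over all calls and -1.52 points (SE 0.484) with 1 call per position. Windows that differed numbered 11 of 24418 in fetus, 4 higher and 7 lower in Aid, 4 of 24331 in placenta, 1 higher and 3 lower, and 6 of 21681 in sperm, all lower. Against the genome-wide difference 7 windows differed in fetus, 5 higher and 2 lower. Counting each position once, 1, 2 and 2 windows differed. The share of all cytosine calls includes unconverted ones. At CC the methylated share was lower in Aid than in WT: 0.104% against 0.310% in fetus, 0.0796% against 0.166% in placenta, and 0.139% against 0.510% in sperm. The median window difference in sperm was -0.392 points, so small falls in Aid windows were not told apart from unequal conversion. The 5 named falls in sperm were larger, from -13.9 to -34.2 points. At the depth of fetus, a 3-fold change was recovered in 8% of the changed windows of simulated libraries. WT and Aid libraries of these tissues came from different flow cells, so genotype and sequencing batch cannot be told apart in them, while the 4 PGC libraries shared both of their flow cells.

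The windows that differed outside PGCs included the ribosomal RNA gene copy in all 3 tissues. In the window of chromosome 17 from 39900001 to 40000000 the methylated share of calls was 10.2% of 420 in Aid fetus and 24.3% of 1992 in WT, 10.3% of 1217 and 17.7% of 1430 in placenta, and 19.4% of 1121 and 33.7% of 912 in sperm. The window of the X chromosome from 166400001 to 166500000 had a lower share of all cytosine calls in Aid fetus (7.14% of 154 calls against 24.2% of 839) and in Aid placenta (5.64% of 461 against 16.2% of 402). At the X end within it, the CpG level of fetus was not lower in Aid, at 100% of 6 CpG calls against 93.3% of 149, while that of placenta was 48.6% of 37 against 70.7% of 41. At the ribosomal RNA gene copy the CpG levels were 34.95% and 59.9% in Aid and WT fetus, 25.5% and 48.2% in placenta, and 48.8% and 73.5% in sperm. Relative to depth, the Aid libraries also had fewer calls at this copy, 0.238 times WT in fetus, 0.527 in placenta and 0.600 in sperm. A lower level of the same copies was therefore not told apart from uneven recovery of the copies. On chromosome 9 from 31300001 to 31400000 Aid fetus was higher (34.9% of 585 calls against 2.67% of 150), and so was Aid placenta (16.4% of 293 against 1.90% of 158). In Aid fetus 458 of these calls lay at 10 positions of 1 kb, and without positions called over 10 times the difference was -0.304 points. With 1 call per position the ribosomal window kept its call in fetus and placenta but not in sperm (difference -8.85 points, adjusted p = 0.286 in Fisher's exact test), and the X window in placenta but not in fetus (-13.0 points, adjusted p = 0.422 in the same test). The window on chromosome 9 lost its call in both tissues.

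**Figure D3:**
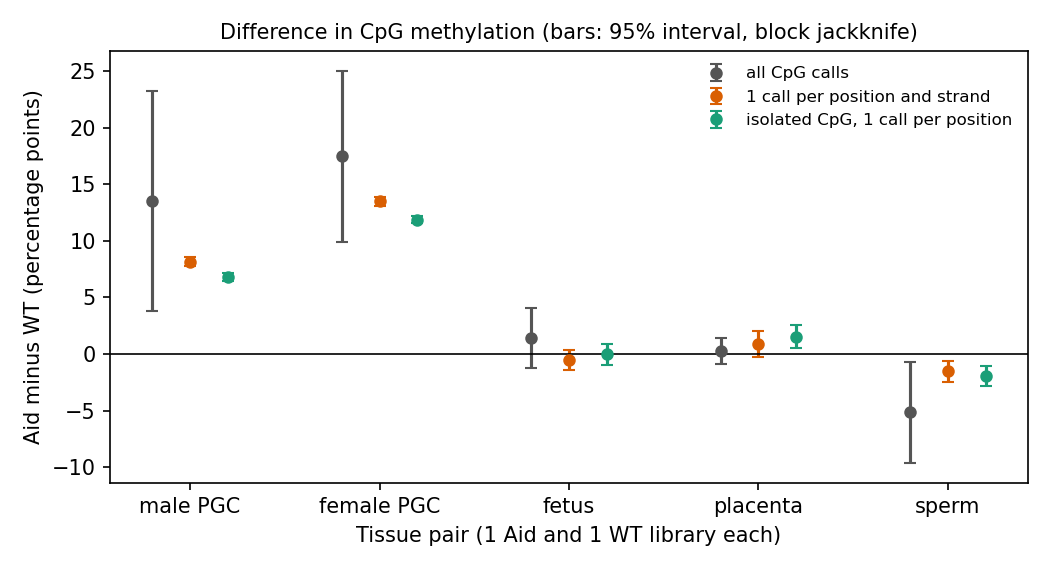
Aid minus WT difference in CpG methylation (percentage points) of the 5 tissue pairs, for all CpG calls, 1 call per position and strand, and isolated CpG sites with at most 30 calls and 1 call per position. Bars are 95% intervals from the block jackknife, which cover variation along the genome and not between animals. Both PGC pairs lie above 0 under each choice, from 6.79 to 17.5 points.

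Over the 5 tissue pairs the mean Aid minus WT difference was 5.50 points, with 4 of 5 pairs above 0 (exact sign-flip permutation test, two-sided, p = 0.3125; the smallest p that 5 pairs allow is 0.062). The mean difference of the 2 PGC pairs exceeded that of the other 3 pairs by 16.7 points (exact permutation of the pair labels, two-sided, p = 0.1, the smallest that 10 splits allow). Counted once per position, these values were 4.10 points (3 of 5 pairs above 0, exact p = 0.375) and 11.2 points (exact p = 0.1).

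Np95-deficient ES cells, a reference for low methylation, had lost most CpG methylation. Their level was 19.8% (SE 2.02) against 82.0% in WT ES cells, a difference of -62.2 points (SE 3.70), and -57.9 points (SE 0.502) with 1 call per position. The loss was seen on 19 of 19 autosomes, from -51.7 points (SE 1.97) on chromosome 5 to -62.1 (SE 1.78) on chromosome 3. At the satellite regions 11.1% of 5967 CpG calls were methylated in Np95-deficient cells and 87.0% of 7597 in WT cells, and at the ribosomal RNA gene copy 1.65% of 121 and 13.2% of 114. Of 24647 windows 1145 differed, all lower without Np95. The largest falls were in 2 windows, on chromosome 2 from 98500001 to 98600000 (3.89% of 17243 calls against 27.3% of 21252) and on chromosome 12 from 3100001 to 3200000 (3.19% of 752 against 23.03% of 964). Both hold satellite regions, and with 1 call per position neither kept its call (differences -1.68 and -6.44 points). Against the genome-wide difference 14 windows differed, 8 higher and 6 lower, and thinned to the shallowest library 5 differed. Counted with 1 call per position, 544 windows differed. At 1 call per position the level of Np95-deficient cells, 22.4% (SE 0.342), stood beside 22.9% (SE 0.577) in Aid female PGCs, 25.3% (SE 0.497) in Aid male PGCs, and 17.2% and 9.45% in WT male and female PGCs, without a test between these cell types.

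Neighbouring CpG sites of 1 molecule were methylated together in PGCs, a measure chosen after seeing the data. Pairs of calls on 1 strand at most 15 bp apart, at positions called once, were taken as calls of 1 molecule. Given a methylated first call, the second was methylated in 87.7% (SE 0.640) of cases in WT male PGCs and 86.3% (SE 0.826) in WT female PGCs, where the level of the same calls was 18.7% and 12.3%. In Aid male and female PGCs the values were 91.0% (SE 0.386) and 90.3% (SE 0.467) at levels of 28.6% and 26.4%. Np95-deficient ES cells had 54.8% (SE 2.79) at a level of 24.3%, and WT fetus 88.9% (SE 0.750) at a level of 71.9%. Between the strands of an isolated CpG, called on different molecules, the value was 17.6% (SE 1.05) in WT male and 11.5% (SE 1.41) in WT female PGCs, at levels of 15.2% and 6.54%, and 24.0% (SE 0.974) and 22.3% (SE 1.11) in Aid male and female PGCs, at levels of 21.8% and 18.7%. At CpG that are not isolated, as neighbours are, the opposite strand exceeded the level by more, 9.87 points (SE 2.62) in WT male, 18.2 (SE 1.69) in Aid male, 17.5 (SE 3.65) in WT female and 17.9 (SE 2.14) in Aid female PGCs.

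**Figure D4:**
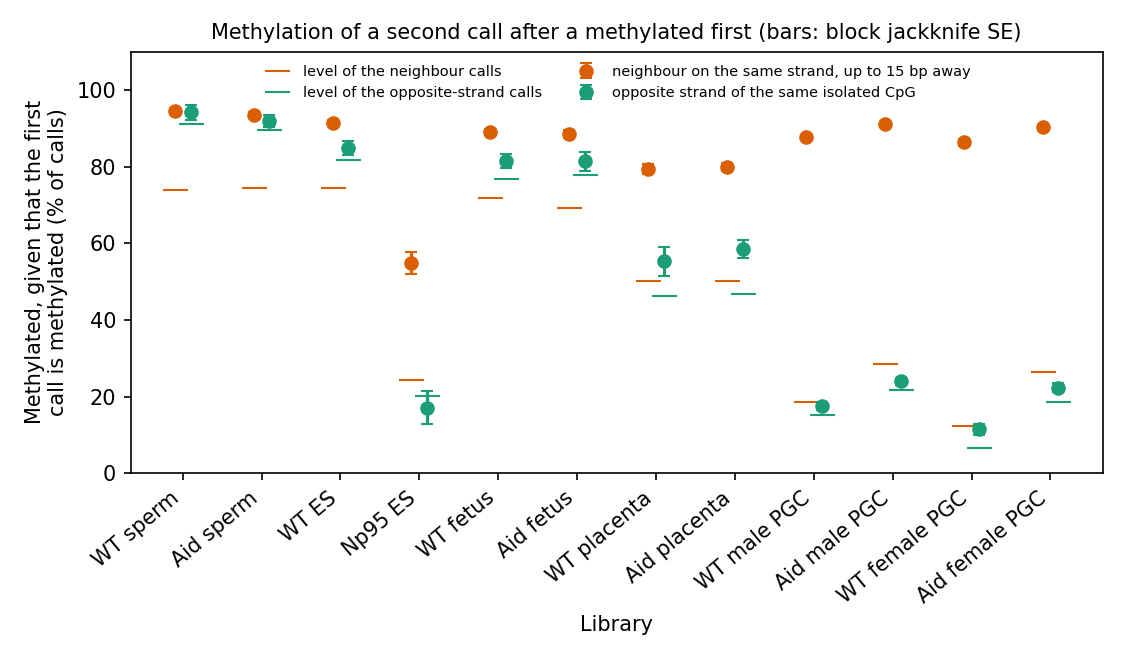
Share of second calls that were methylated (percent), given a methylated first call, in the 12 libraries, for a neighbouring CpG on the same strand up to 15 bp away and for the opposite strand of the same isolated CpG. Points are shares with block jackknife SEs and dashes are the methylation level of the same calls. In the 4 PGC libraries the neighbour values lie between 86.3% and 91.0%, far above their dashes, while the opposite-strand values lie between 11.5% and 24.0%, near theirs.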

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

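The tests between the sexes, at CWG and of the explanations below were chosen after the results were seen. The Aid minus WT difference was larger in female than in male PGCs, by 3.93 points over all CpG calls (SE 1.55), 5.32 points with 1 call per position and strand (SE 0.261) and 5.09 points at isolated CpG with at most 30 calls and 1 call per position (SE 0.249), from the block jackknife over the 4 libraries. This stands out because the effect of 1 contrast differed between the sexes. As a mean over windows of 100 kb the order turned, with 5.69 points in males over 27 windows and 5.44 in females over 29. Each sex and genotype had 1 library, so the error covers variation along the genome and not between animals. In sperm the Aid minus WT difference was -5.15 points over all calls, below 0 where both PGC pairs were above 0. It was smaller with 1 call per position, at -1.52, and as a mean over windows of 10 Mb with 1 call per position, at -0.543. It was larger as a mean over 6 windows of 100 kb, at -11.5, at positions called in both libraries, at -11.3, and on the plus strand, at -6.75. The difference between sperm and PGCs was not tested on its own. Outside CpG, the methylated share at CWG exceeded that at CC by 1.20 points in WT ES cells (SE 0.0472) and 1.03 points in Np95-deficient ES cells (SE 0.0482), 1 call per position, against 0.241 points in WT fetus (SE 0.0252) and 0.253 in Aid fetus (SE 0.0221). WT sperm also had more than fetus, 0.635 points (SE 0.0575), while Aid sperm had 0.282 (SE 0.0246). The ES and WT sperm libraries were those with the highest methylated share at CC (0.659%, 1.12% and 0.510%), so incomplete conversion was not told apart from methylation at CWG. CpG sites with an uncalled base can also enter the CWG class, and their share was not measured. Such a leak would follow the CpG level, which argues against it as the whole cause in the ES cells. With 1 call per position the CpG level was 80.3% in WT and 22.4% in Np95-deficient ES cells. It was 76.7% in WT and 76.2% in Aid fetus, where the CWG excess was smaller than in either ES library.

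The pattern weighed first is the higher CpG methylation of the Aid PGC libraries. Incomplete conversion spread evenly over the genome was argued against, since the methylated share at CC differed by at most 0.0339 points between Aid and WT PGCs. More calls at methylated sites that are CpG-dense among identified sites were argued against as the whole cause. Isolated CpG with 1 call per position still differed by 6.79 points in males, the smaller of both differences. Neighbours that were not identified are not seen, so recovery that rises with true CpG density was not excluded. A share of fetus-like molecules was argued against as the whole cause, since the share of neighbouring CpG pairs with only 1 CpG methylated differed from that of such a mixture by -1.54 points in males (SE 0.352) and -1.21 in females (SE 0.374), but the bound was tightened after this value was seen and a looser one tried first would have kept the mixture. Gain at single CpG independent of neighbours was argued against by a gap of -15.8 points (SE 0.975). An effect of genotype on erasure, a difference in stage or purity between the libraries, and a mixture combined with uneven recovery stay open, as each group had 1 library.

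The pattern weighed next is the excess of calls, relative to depth, in CpG-dense methylated regions of the Aid PGC libraries, 3.82 and 3.09 times WT at the ribosomal RNA gene copy in males and females. More copies of these regions in the Aid line would raise the Aid to WT ratio outside PGCs too, but this could not be decided. There the ratio was at most 0.781 at the ribosomal and X regions. At 5 further CpG-dense regions, also chosen after their values were seen, it was 0.310 in fetus, 0.793 in placenta and 1.08 in sperm. In male and female PGCs it was 2.46 and 1.88 there. Genotype and flow cell coincide outside PGCs, and the fetus ratio itself fell with CpG density, so extra copies could be hidden. Recovery that rises with CpG density stays open: at sites with at most 30 calls the ratio of calls, Aid to WT, was 2.16 times higher with over 5 other CpG than at isolated sites in females, the smaller of both pairs, but this repeats the pattern at other sites and does not test its cause. In fetus the ratio fell instead, from 0.724 at isolated sites to 0.202 with over 5 other CpG. Neither a difference in preparation nor a biological explanation was tested.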

How the results depend on the processing

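The Aid minus WT difference stayed above 0 in both PGC pairs under every alternative run, from 5.69 to 16.8 points in males and 5.44 to 19.7 in females, while that of fetus changed sign in 6 and that of placenta in 3. Some male values had large block errors and were not clear of 0, with 11.4 points (SE 5.84) on the plus strand. At positions called in both libraries the male value was 13.7 points (SE 7.13). Of 132 differences under alternatives, 37 moved by less than counting error, 89 by more, and 6 turned from a value beyond counting error, all in fetus. Of the other values, 31 of 104 levels, 44 of 126 classes and 47 of 90 window counts stayed close, and 192 of 269 values of named windows kept direction and call, 72 lost the call and 5 turned. The subtraction of the CC share, the 30-call limit, isolated CpG, the outside strand, windows of 10 Mb, and window counts without heavily called positions or CC calls were chosen after seeing the data. Promoter and gene-list alternatives were not run, for lack of an mm9 annotation here. Means over windows of 100 kb rest on 6 to 48 windows, which hold the repeated regions. Depth limits the window counts, since thinned libraries have fewer methylated calls per window. Beyond that the cause was not tested.

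All values below are in percentage points. The 30-call limit, isolated CpG and windows of 10 Mb were each combined with 1 call per position, so their values are to be set against those of 1 call per position alone. When each position counted once the differences were 8.17 (male PGC), 13.5 (female PGC), -0.526 (fetus), -1.52 (sperm), -57.9 (ES), -59.6 (male PGC less fetus), -67.3 (female PGC less fetus), -7.72 (WT female less male) and -2.40 (Aid female less male). Without positions called over 10 times the differences were 8.75 (male PGC), 14.9 (female PGC), -0.171 (fetus), -1.59 (sperm), -57.9 (ES), -56.5 (male PGC less fetus), -64.0 (female PGC less fetus), -7.51 (WT female less male) and -1.39 (Aid female less male). As a mean over windows of 100 kb the differences were 5.69 (male PGC), 5.44 (female PGC), -4.65 (fetus), -6.21 (placenta), -11.5 (sperm), -61.0 (ES), -26.4 (male PGC less fetus), -30.1 (female PGC less fetus), -2.86 (WT female less male) and -2.11 (Aid female less male). On autosomes the differences were 12.6 (male PGC), 16.1 (female PGC), -52.7 (female PGC less fetus), -5.49 (WT female less male) and -1.99 (Aid female less male). On the plus strand the differences were 11.4 (male PGC), 15.7 (female PGC), -6.75 (sperm), -66.0 (ES), -45.2 (male PGC less fetus), -6.16 (WT female less male) and -1.79 (Aid female less male). On the minus strand the differences were 16.8 (male PGC), 19.7 (female PGC), -0.632 (placenta), -3.11 (sperm), -57.1 (ES), -49.0 (male PGC less fetus), -3.11 (WT female less male) and -0.138 (Aid female less male). In the first run the differences were 14.2 (male PGC) and 17.8 (female PGC). In the second run the differences were 12.8 (male PGC) and 17.02 (female PGC). Counting each position once and without sites called over 30 times the differences were 8.18 (male PGC), 13.5 (female PGC), -0.293 (fetus), 1.27 (placenta), -1.57 (sperm), -58.2 (ES), -60.8 (male PGC less fetus), -68.6 (female PGC less fetus), -7.87 (WT female less male) and -2.51 (Aid female less male). At isolated CpG with at most 30 calls, and 1 call per position, the differences were 6.79 (male PGC), 11.9 (female PGC), -0.0325 (fetus), 1.54 (placenta), -1.97 (sperm), -59.4 (ES), -62.8 (male PGC less fetus), -71.1 (female PGC less fetus), -8.33 (WT female less male) and -3.25 (Aid female less male). With the opposite strand called outside the pair the differences were 13.9998 (male PGC), -44.9 (male PGC less fetus), -49.7 (female PGC less fetus), -4.73 (WT female less male) and -1.43 (Aid female less male). Counting each position once, as a mean over windows of 10 Mb, the differences were 8.07 (male PGC), 13.5 (female PGC), -0.0504 (fetus), -0.543 (sperm), -57.9 (ES), -60.2 (male PGC less fetus), -68.2 (female PGC less fetus), -7.69 (WT female less male) and -2.30 (Aid female less male). At positions called in both libraries the differences were 16.7 (female PGC), 3.84 (fetus), -0.589 (placenta), -11.3 (sperm), -74.5 (ES), -39.5 (male PGC less fetus), -45.1 (female PGC less fetus) and -1.39 (Aid female less male). With the CC share subtracted the differences were -63.0 (ES).

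With at least 100 calls, windows numbered 2 (sperm). In windows of 20 kb, windows numbered 1824 (male PGC), 4625 (female PGC), 6 (fetus), 1 (placenta), 1 (sperm), 14 (ES), 2346 (male PGC to fetus), 5230 (female PGC to fetus) and 339 (WT female to male). In windows of 500 kb, windows numbered 4579 (female PGC), 5 (fetus), 10 (sperm), 3200 (ES), 4918 (male PGC to fetus), 4995 (female PGC to fetus) and 733 (Aid female to male). Counting each position once, windows numbered 1027 (male PGC), 1 (fetus), 2 (placenta), 2 (sperm), 544 (ES), 848 (WT female to male) and 43 (Aid female to male). Thinned to the shallowest library, windows numbered 5 (male PGC), 5 (female PGC), 1 (fetus), 0 (placenta), 1 (sperm), 5 (ES), 4 (male PGC to fetus), 8 (female PGC to fetus), 1 (WT female to male) and 0 (Aid female to male). Tested against the genome-wide difference, windows numbered 679 (male PGC), 1150 (female PGC), 7 (fetus), 14 (ES), 67 (male PGC to fetus), 221 (female PGC to fetus) and 386 (WT female to male). Without positions called over 10 times, windows numbered 2 (placenta). Without CC calls, windows numbered 3 (sperm).

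The mean over the 5 tissue pairs turned to -2.24 points as a mean over windows of 100 kb (exact sign-flip permutation p = 0.5625). Named windows turned on the X chromosome from 146800001 in female PGCs (1.76 with 1 call per position, 3.85 without positions called over 10 times) and, without such positions, on chromosome 16 from 57300001 (-3.38) and 17 from 86000001 (0.0991) in male PGCs and 9 from 31300001 in fetus (-0.304). Among classes whose difference over all calls exceeded counting error, those that turned were fetus autosomes (-0.458 with 1 call per position, -0.284 also without sites called over 30 times), isolated placenta CpG (-2.59 at positions called in both libraries) and sperm CpG with 2 others within 100 bp (7.28 and 7.498 under the same settings as fetus). Classes within counting error changed sign too, such as fetus CpG with 3 to 5 others, from 3.81 to -16.2 with 1 call per position, and density classes higher in Aid outside PGCs numbered 3 of 15 with 1 call per position, with or without the 30-call limit, against 5 over all calls. The cause was not tested.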

Other observations

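The tests of the X chromosome and of neighbouring CpG in this part were chosen after the results were seen. Methylation of the X chromosome stood above that of the autosomes in the female PGC libraries. Among sites with at most 30 calls, with 1 call per position, the X minus autosome difference was 8.31 points (SE 3.68) in WT and 11.2 points (SE 3.81) in Aid female PGCs, and 5.40 (SE 4.81) and 6.33 (SE 5.64) in WT and Aid male PGCs. Sites of the X end with at most 30 calls were kept in, so an excess along the whole chromosome was not shown. In placenta the X was lower than the autosomes in WT, by -7.09 points (SE 3.01), and differed by -1.81 points (SE 2.72) in Aid. The difference between the sexes was not tested. The ribosomal RNA gene copy had a methylation of 13.2% of 114 CpG calls in WT ES cells, against 73.5% of 366 in WT sperm and 48.2% of 448 in WT placenta. The Aid libraries of these tissues had 48.8% of 377 in sperm and 25.5% of 376 in placenta. Relative to depth, WT ES cells also had fewer calls at this copy than WT sperm and WT placenta. A difference between tissues was therefore not told apart from uneven recovery of the copies.

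Neighbouring CpG of 1 molecule were methylated together in PGCs. Methylation kept at fixed sites would also make the opposite strand methylated, and is argued against as the whole cause: at CpG that are not isolated the excess of the opposite strand over the level was at most 18.2 points (SE 1.69, Aid male PGCs), against at least 62.4 points (SE 0.664, Aid male PGCs) between neighbours. This excess was larger than at isolated CpG, where it was at most 4.96 points (SE 1.38, WT female PGCs), so fixed sites stay open for a part, and a stricter bound used first for isolated CpG was met here by the values alone but not with its margin of 3 SE. Reads that escaped conversion evenly over the genome are argued against by the methylated share at CC. It was at most 0.145% in the PGC libraries, where at least 10.6% of neighbouring pairs had both CpG methylated. CC was not measured on the reads of these pairs, so escape confined to CpG-dense reads was not tested. What keeps neighbours together was not tested.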
